A study of Homo sapiens with 6 samples.

How the data were processed

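Huh7 cells were profiled by RNA sequencing in 4 libraries and by DDX21 ChIP in 2, the ChIP and its input, with 1 library in each of 6 groups. Per the labels, RNA came from cells infected with an empty or a FAM99B lentivirus, and from cells transfected with a control siRNA or an siRNA to DDX21 for 48 h. RNA libraries were made with an Illumina kit for polyadenylated mRNA and read paired-end. The submitters' processing notes name Bowtie, Picard, deepTools and MACS2, without versions, and build hg38. They do not give the aligner or the counting tool of the RNA libraries. The protocol text for the chromatin libraries names ChIP-seq and, in places, CUT&Tag, and the columns of the peak table are those of MACS version 1 output rather than MACS2.

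The deposited count tables hold raw whole-number counts per gene, which were tested to be unscaled. The deposited FPKM tables hold counts per kilobase of a fixed length per gene and scaled to the total counts of the library, tested against the counts. The deposited ratio columns are the FPKM of the treated library over that of the control after adding 0.1 to each, and cover mRNAs with a summed FPKM above 1. The authors' shorter tables hold exactly the genes at or beyond a ratio of 1.5 or 0.67. In the deposited peak table, each peak has a count of ChIP tags, a score of -10 times log10 of the peak caller's p, a ratio over the local background (fold enrichment) and a false discovery rate in percent. Peaks outside genes and beyond 1500 bp upstream of a start are absent from that deposited table, so no share of the genome could be given. Positions are 1-based in hg38, and the deposited lengths in bp equal end minus start plus 1.

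Choices such as groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined. The label of the siRNA control sample conflicts with itself: its description carries the name of the first DDX21 siRNA, while its title and treatment give the control. The column named as control was taken for it, and the second siRNA's column for the knockdown sample. The per-sample columns of the remaining siRNA library, in 7 tables, match no sample and were not used, so 1 library was left out. The first siRNA enters only through the authors' deposited ratio column, which has no counting interval and no TMM scaling. Rows numbered 54261, of which 511 on chromosome Y or of X-inactivation RNAs were left out. Older symbols were turned into current ones by gene number and by a table of older names, giving 49342 rows with a current symbol. In the peak table, 87 rows have a gene name turned into a date by a spreadsheet and could not be assigned.

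Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3) on the 2 libraries of each comparison. The ratio of scaled counts has an exact interval at 95% from the conditional binomial (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). It covers counting error alone, and without replicates no p-value was computed. A gene was tested with at least 20 counts over the 2 libraries and called at a ratio of at least 1.5 or at most 1/1.5 with an interval excluding 1. A count of 0 was set to 3 for a bound. On data simulated from the control library with 200 genes changed, each with a mean of at least 50 counts, the rule recovered 99.5% at 2-fold and 100% at 4-fold in the FAM99B comparison, and 98.5% and 100% in the knockdown. Intervals covered the true ratio for 95.3 to 95.7% of genes. The floor of 3 counts is 0.0547 CPM in the vector control, 0.0572 in the FAM99B library, 0.173 in the siRNA control and 0.190 in the knockdown, so the siRNA libraries are the less precise. The 10 most abundant genes took 6.30, 5.61, 7.67 and 6.92% of counts in that order.

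There were 36 fixed gene lists, and the 2 of cytosolic ribosomal proteins were also joined into 1. For each list the median log2 ratio was set against 10000 random lists with the same number of members, matched on 20 bins of mean expression and on mRNA or not. A second matching used 10 bins of expression and 10 of transcript length, the length being recovered from the authors' FPKM. Overlaps were compared with the product of the list sizes over the number of genes. The 2 siRNAs share 1 control library. In 100 draws of libraries without change, counting error alone gave the overlap reported beside theirs, and a difference between cultures, which that control would also bring into both ratios, was not measured.

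Genes were named by rule: FAM99B, FAM99A, DDX21 and DDX50 in every RNA library; the 10 highest and 10 lowest ratios per comparison with at least 100 counts in the higher library and an interval that excludes 1.5-fold; up to 4 members per list with the largest ratio and at least 100 counts; 6 genes per direction called in both comparisons; the 10 peaks of largest deposited fold enrichment and the 4 largest at ribosomal protein promoters; and up to 6 genes per direction in all 3 of the authors' ratio columns. Some genes that the rule selects are not reported here. Other genes given as examples of promoter peaks were chosen after their values were seen. A promoter peak is one with any part within 1 kb of a transcription start in the authors' annotation. Its share per list was set against random lists matched on expression in the siRNA control library. Genes with and without a promoter peak were compared within 10 bins of expression, with 1000 bootstrap draws of genes.

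Alternatives were scaling by total counts or by the size factors of DESeq2 1.42.0; no minimum or at least 100 counts; 5 counts added before the ratio; the authors' FPKM with 0.1 or 1 added; a limit of 2-fold, or the whole interval beyond 1.5-fold; promoter windows of 3 kb and 100 bp; and peaks of at least 5-fold, or the upper part by enrichment. Restriction to mRNAs, the first siRNA in place of the second and matched lists for peaks of at least 5-fold were added after the data were seen. Figures were drawn with matplotlib 3.10.9.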

Results

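The series measured RNA and chromatin in Huh7, a human hepatocellular carcinoma line, around 2 genes: FAM99B, a long noncoding RNA expressed in liver, and DDX21, a DEAD-box RNA helicase of the nucleolus and nucleoplasm that acts in ribosomal RNA synthesis and processing. There were 4 RNA libraries and 2 chromatin libraries. Cells carrying an empty lentivirus (54837446 counts) were set against cells carrying a FAM99B lentivirus (52447391 counts). Cells given a control siRNA (17311641 counts) were set against cells given an siRNA to DDX21, 48 h after transfection (15777867 counts). A DDX21 ChIP library had 1 input library. Each group had 1 library, so there were no replicates: every interval below covers counting error only, and every ratio compares these libraries, not the conditions.

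FAM99B, the RNA that was overexpressed, had 4237 counts in the overexpression library and 16 in the vector control, a ratio of 272 (95% counting interval 167 to 477). It was near absent in both siRNA libraries, with 6 counts in the control and 3 in the DDX21 knockdown. The FAM99B gene is annotated as a lncRNA on chromosome 11 at 1683270 to 1685629. Its neighbour and paralog FAM99A (chromosome 11, 1665599 to 1667856) had 136 counts against 9, a ratio of 15.5 (7.95 to 34.7), and reads shared between the 2 sequences could not be separated. DDX21 (chromosome 10, 68956170 to 68985068, protein coding) had a ratio of 1.00 (0.979 to 1.03) in the FAM99B comparison. In the knockdown it had 2008 counts against 4929, a ratio of 0.448 (0.425 to 0.472). DDX50, the paralog beside it (chromosome 10, 68901315 to 68946847), had ratios of 0.919 (0.861 to 0.981) with FAM99B and 1.05 (0.942 to 1.17) with the knockdown.

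With FAM99B overexpressed, the mRNAs and lncRNAs with the highest ratios after FAM99B and FAM99A, among those with at least 100 counts in 1 of the libraries, included chemokine, receptor and NF-kB target genes. BIRC3, an inhibitor of apoptosis induced by NF-kB, was 9.43-fold higher (6.64 to 13.8), and UBD, a ubiquitin-like modifier, 8.01-fold (6.52 to 9.94). The neutrophil chemokine CXCL5 was 5.06-fold higher (4.69 to 5.46), the protease CTSE 5.05-fold (3.50 to 7.49) and the chemokine receptor CXCR4 4.96-fold (3.83 to 6.52). GPRC5A, an orphan receptor, had a ratio of 4.82 (3.21 to 7.47), the natriuretic peptide gene NPPB 4.65 (4.12 to 5.25) and OLR1, a receptor for oxidised LDL, 4.49 (3.42 to 5.95).

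Under the same count limit, low ratios with FAM99B included those of the neural transcription factor POU3F2 (0.380, 0.259 to 0.548), the histone genes H2AC19 (0.380, 0.266 to 0.535) and H2AC18 (0.470, 0.348 to 0.629), and DLK1, a membrane relative of the Notch ligands (0.433, 0.396 to 0.474). The myosin gene MYO1F was at 0.446 (0.355 to 0.557), the lncRNA LOC105375103 at 0.460 (0.355 to 0.593) and HPR, the haptoglobin-related protein, at 0.472 (0.371 to 0.596). Linker histone H1-2 was at 0.472 (0.458 to 0.486), H4C8 at 0.489 (0.438 to 0.545) and the actinin gene ACTN3 at 0.495 (0.406 to 0.601). Histone genes share near-identical coding sequence, so reads may have passed between members of the family.

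By list, of 16 measured NF-kB and inflammatory genes, 9 were higher, 0 lower and 7 neither, with a median log2 ratio of 0.82. The chemokines CXCL3 (4.26), CXCL8 (3.50) and CXCL2 (3.01) stood beside BIRC3. Of 14 immediate early genes, which respond within minutes to growth signals, 5 were higher and 0 lower (median 0.47), among them FOSB (2.00), FOSL1 (1.98), ATF3 (1.67) and DUSP1 (1.66). Of 22 mesenchymal and matrix genes, 6 were higher and 0 lower (median 0.24): TAGLN was at 2.28, CCN1 at 2.10 and VIM at 1.53. Of 21 genes of the integrated stress response, 4 were higher and 0 lower (median 0.18): VLDLR (1.77), CHAC1 (1.74), ATF3 (1.67) and NUPR1 (1.60).

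Lists with low medians in the FAM99B library included the replication-dependent histone genes, whose mRNAs are made in S phase and mostly lack a poly(A) tail: 0 of 14 were higher and 10 lower (median -0.66), with H2BC8 at 0.544 and H2AC8 at 0.616. Of 24 cell cycle G1/S genes 0 were higher or lower, with a median of -0.17 (MCM5 0.806, E2F1 0.851), while the 25 G2/M genes had a median of 0.03. Among 37 hepatocyte markers, 0 were higher and 4 lower (median -0.25): the plasma protein HP (0.572), the urea cycle enzyme CPS1 (0.589), the fetal albumin relative AFP (0.640) and the plasma protein AHSG (0.666). No member of 17 ER unfolded protein response genes passed the rule, with a median of -0.18 (HSPA5 0.788). The 13 mitochondrially encoded mRNAs also had 0 calls, at a median of -0.19 (MT-ND1 0.731).

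Genes of ribosome synthesis, the subject of the series, moved little in the FAM99B library. None of 79 cytosolic ribosomal protein genes passed the 1.5-fold rule, and their median log2 ratio was -0.10. The counting interval lay below 1 for 65 of them and above 1 for 6. RPL37 was at 0.700 (0.686 to 0.714), RPL39 at 0.728 (0.667 to 0.794), RPS29 at 0.758 (0.729 to 0.788) and RPS21 at 0.787 (0.768 to 0.807). The median lay below all 10000 random lists matched on expression, 95% of which fell between -0.06 and 0.00. When the random lists were also matched on transcript length it stood at percentile 6.76. The 107 ribosome biogenesis factors had 0 higher, 0 lower and a median of -0.04 (NMD3 1.25, IMP4 0.874), the 76 mitochondrial ribosomal proteins 0 calls and a median of -0.08 (MRPL23 0.748). The 15 genes of the RNA polymerase I machinery had a median of -0.00 and 0 calls, and this median turned to 0.02 when counts were scaled by library totals.

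Across all genes, 613 of 18930 tested were higher and 306 lower in the FAM99B library. A gene was called when it had at least 20 counts over the 2 libraries, a ratio of at least 1.5 or at most its inverse, and a counting interval that excluded 1. On data simulated with counting error and no change, the same rule called 92 genes higher and 96 lower of 18839. With at least 100 counts required, 371 were higher and 157 lower, and with at least 2-fold 253 and 109.

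**Figure D1:**
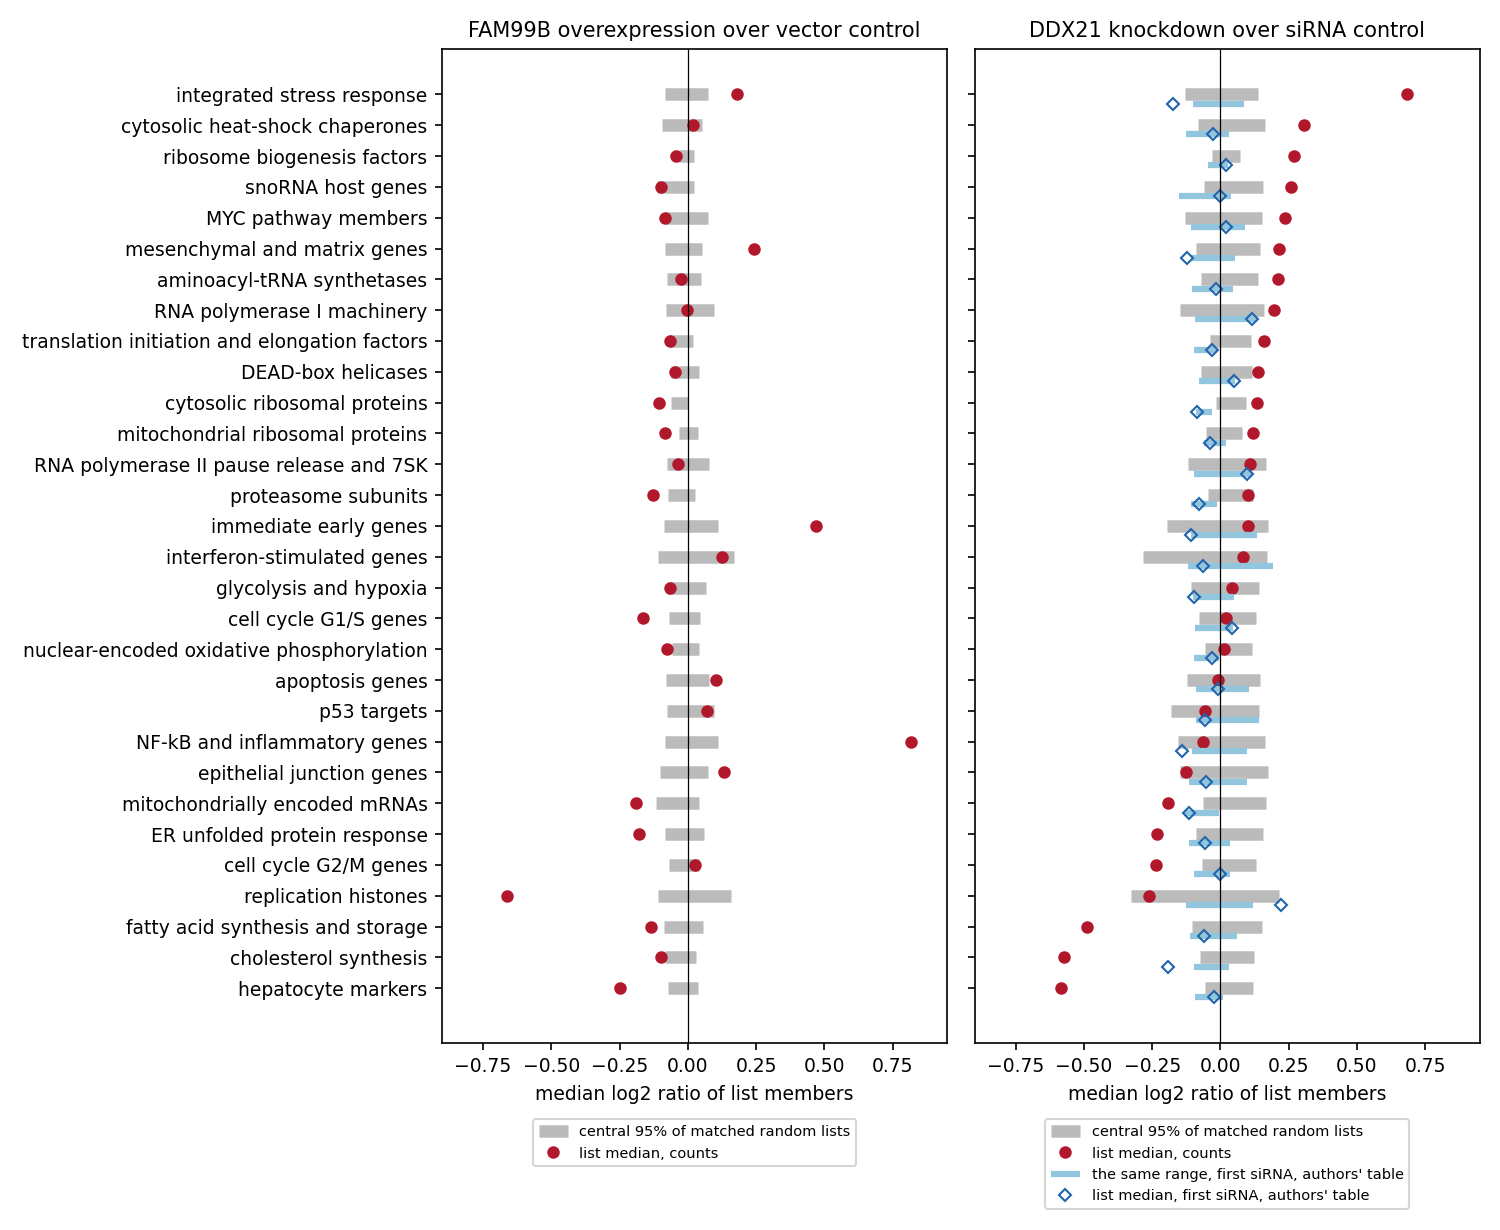
Median log2 ratio of each fixed gene list in the FAM99B comparison (left) and the DDX21 knockdown (right), with the range that holds 95% of random lists matched on expression. Open diamonds show the first DDX21 siRNA from the authors' deposited table with its own matched range. On the left, NF-kB genes (high) and replication histone genes (low) stand out, and on the right stress-response, hepatocyte and cholesterol genes.

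With DDX21 knocked down, the highest ratio among mRNAs and lncRNAs with at least 100 counts in 1 of the libraries was that of CIDEC, a lipid droplet protein, at 6.12 (4.30 to 8.94). A first siRNA to DDX21 is used here only through its ratios in the authors' deposited table, where DDX21 itself was at 0.269, and its ratio follows each gene here: CIDEC was at 1.18. The cytochrome P450 gene CYP1B1 was at 4.99 (3.19 to 8.13; first siRNA in the authors' deposited table at 1.61), the hexokinase-like HKDC1 at 4.70 (3.12 to 7.31; 0.999) and the reductase AKR1B10 at 4.20 (3.06 to 5.86; 1.20). COTL1, an actin-binding protein, was at 3.86 (2.90 to 5.19; in the authors' deposited table at 1.36), the secreted glycoprotein STC2 at 3.54 (3.05 to 4.12; 0.886) and SPP1, osteopontin, at 3.32 (2.89 to 3.82; 1.08). The AP-1 subunit FOSL1 was at 3.14 (2.63 to 3.77; in the authors' deposited table at 0.643), the acyl-CoA synthetase ACSL5 at 3.03 (2.45 to 3.77; 1.31) and the spindle protein MISP at 3.03 (2.31 to 4.01; 0.904).

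Under the same count limit, several low ratios of the knockdown were those of liver enzymes and transporters. The urea cycle enzyme ARG1 was at 0.123 (0.0670 to 0.210; first siRNA in the authors' deposited table at 0.512), the steroid dehydrogenase HSD17B2 at 0.134 (0.0822 to 0.210; 0.567) and the citrate transporter SLC13A5 at 0.152 (0.0946 to 0.233; 0.838). The glucose-sensing transcription factor MLXIPL was at 0.195 (0.118 to 0.309; in the authors' deposited table at 0.895), the glutamine transporter SLC38A3 at 0.197 (0.157 to 0.244; 0.749) and YPEL3 at 0.203 (0.134 to 0.299; 0.613). TP53INP1, a p53 target, was at 0.208 (0.156 to 0.273; in the authors' deposited table at 0.486), the histidine-degrading enzyme HAL at 0.214 (0.156 to 0.289; 0.848) and KANK4 at 0.250 (0.174 to 0.353; 1.15).

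By list, hepatocyte markers had 0 of 36 members higher and 17 lower (median -0.58), among them CPS1 (0.259; first siRNA in the authors' deposited table at 1.70), HP (0.428; 1.25), FABP1 (0.441; 0.970) and FGA (0.480; 0.870). Of 25 cholesterol synthesis genes 0 were higher and 12 lower (median -0.57): TM7SF2 (0.288; in the authors' deposited table at 0.871), HSD17B7 (0.375; 0.870), INSIG1 (0.467; 0.849) and MSMO1 (0.468; 0.674). Fatty acid synthesis and storage genes had 1 of 16 higher and 7 lower (median -0.49), with FADS1 at 0.476 (in the authors' deposited table at 0.958) and GPAM at 0.490 (1.39). Of 21 integrated stress response genes 11 were higher and 0 lower (median 0.68), among them ASNS, which makes asparagine (2.99; in the authors' deposited table at 0.653), the cystine transporter SLC7A11 (2.91; 0.671) and VLDLR (2.01; 0.904). Of 22 mesenchymal and matrix genes 4 were higher and 1 lower (median 0.21), with CD44 at 2.43 (in the authors' deposited table at 0.897).

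Lists of ribosome genes had medians above 0 in the knockdown library, though few members passed the rule. With the first siRNA in the authors' deposited table the medians were 0.02 for ribosome biogenesis factors, 0.12 for RNA polymerase I genes and -0.09 for cytosolic ribosomal proteins. Of 107 ribosome biogenesis factors 4 were higher and 0 lower, with a median of 0.27 above all 10000 matched lists, and the interval lay above 1 for 93. The 4 were NOLC1, a nucleolar chaperone of snoRNPs (2.22, 2.12 to 2.32; first siRNA in the authors' deposited table at 1.79), DHX37 (1.67; 1.44), NOL10 (1.66; 1.29) and TCOF1 (1.59; 1.31). Of 25 snoRNA host genes 3 were higher and 0 lower (median 0.26): SNHG19 (1.67), SNHG12 (1.60) and SNHG3 (1.52). The authors' deposited table covers 9 of the host genes, all mRNAs, with medians of -0.00 for the first siRNA and 0.24 for the second. It holds none of the 3 called hosts, so it gives no check on them. Among the 9, DKC1 is also in the list of ribosome biogenesis factors. The 15 RNA polymerase I genes had 0 calls and a median of 0.20 (POLR1B 1.43; in the authors' deposited table at 1.34). Among 79 cytosolic ribosomal protein genes 1 was higher, RPS26 (1.55, 1.33 to 1.80; in the authors' deposited table at 1.34), and 0 lower. Their median was 0.13, at percentile 99.97 of matched lists (95% between -0.02 and 0.09) and 99.91 with length matched too. The interval lay above 1 for 64 and below 1 for 1.

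Lists of protein synthesis beside the ribosome also had medians above 0 in the knockdown library. With the first siRNA in the authors' deposited table the medians were -0.03 for translation factors, -0.02 for aminoacyl-tRNA synthetases, -0.04 for mitochondrial ribosomal proteins and -0.03 for heat-shock chaperones. Each lay within the range of its matched lists, which for translation factors was itself below 0 (-0.10 to -0.01). The difference between the siRNAs was not tested. Of 40 translation initiation and elongation factors 1 was higher, EIF3F (1.59; first siRNA in the authors' deposited table at 1.24), and 0 lower (median 0.16). The 20 aminoacyl-tRNA synthetases had 0 calls and a median of 0.21 (YARS1 1.43; in the authors' deposited table at 0.941), the 76 mitochondrial ribosomal proteins 0 calls and a median of 0.12 (MRPL22 1.40; 1.25). Of 14 cytosolic heat-shock chaperones 2 were higher and 0 lower (median 0.31), HSPA1B (1.84; in the authors' deposited table at 0.945) and HSPA1A (1.51; 1.00). The 25 G2/M genes had 0 calls and a median of -0.24 (CENPE 0.724; in the authors' deposited table at 1.27).

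Across all genes, 758 of 15417 were higher and 1103 lower in the knockdown library by the same rule, against 83 and 68 of 15478 on data simulated with counting error alone. Limits of 100 counts gave 466 and 683, of 2-fold 316 and 500. For the first siRNA, the authors' deposited table listed 312 mRNAs higher and 302 lower, and for the second 522 and 891, of 12212.

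**Figure D2:**
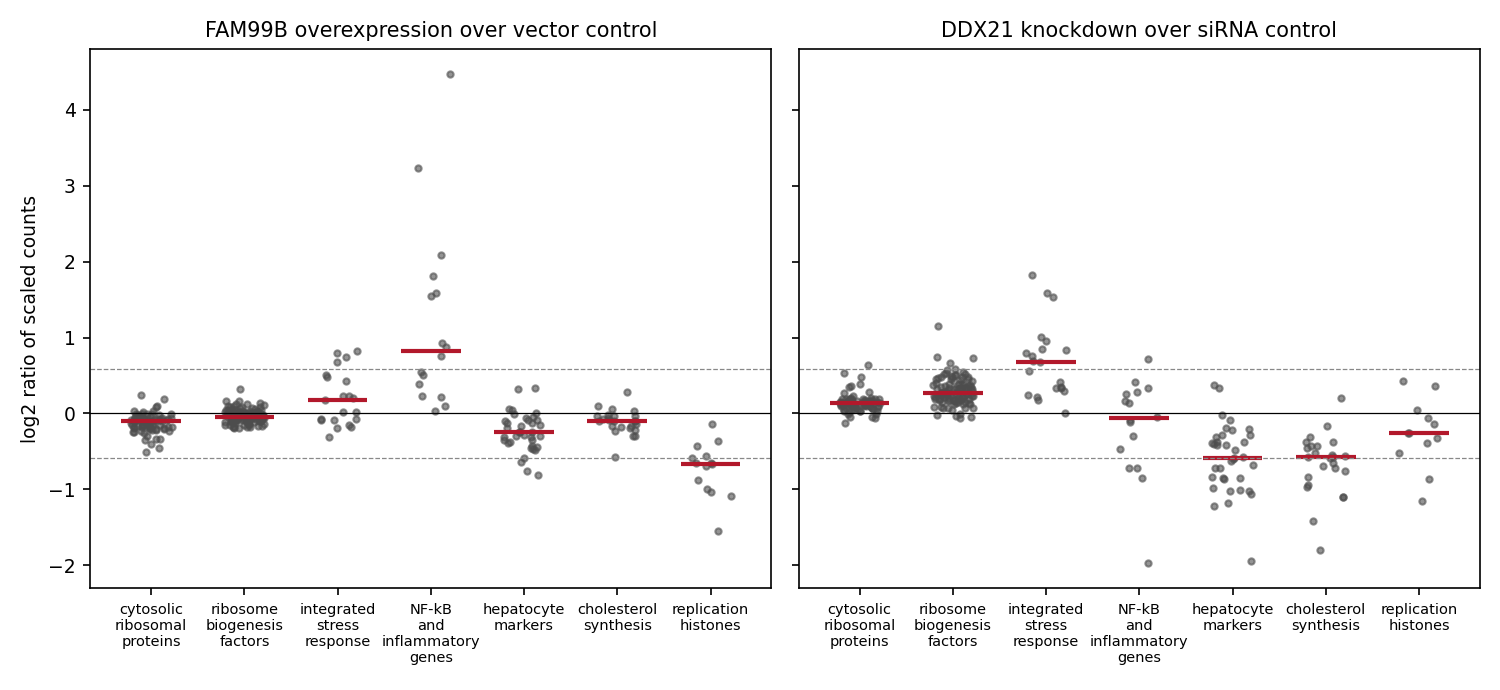
Log2 ratio of every measured member of 7 gene lists in the FAM99B comparison (left) and the DDX21 knockdown (right), with list medians in red and the 1.5-fold limits dashed. Ribosomal protein genes lie close to 0 in both, while a few NF-kB genes on the left and hepatocyte and cholesterol genes on the right lie far from it.

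The 2 siRNAs to DDX21 were compared in the authors' deposited table, where 113 mRNAs were higher and 125 lower with both; independent lists would share 13.3 and 22.0. Opposite ways went 23 and 26 (22.8 and 12.9 for independent lists). Both ratios use the same control library, which alone makes them alike. Libraries simulated without change, with counting error only, shared 29.6 higher and 19.8 lower mRNAs. A difference of the control culture would also enter both ratios and was not measured, so the excess does not show what the siRNAs have in common. The Spearman correlation of the 2 siRNAs in the authors' deposited table was 0.23, and 0.45 in the simulated libraries, while the covariance of the log2 ratios was 0.0338 against 0.0130. The simulated correlation follows from the shared control, as those libraries vary by counting error alone. It therefore cannot show whether the siRNAs were more or less alike than unchanged libraries. The list medians of the first siRNA in the authors' deposited table were 0.02 for ribosome biogenesis factors, -0.02 for hepatocyte markers, -0.19 for cholesterol synthesis and -0.17 for the integrated stress response. The first 2 lay within their matched ranges. The cholesterol median lay below its range (-0.10 to 0.03), as did that of the second siRNA there, -0.58 (-0.06 to 0.14). That shared direction also rests on the same control library. For cytosolic ribosomal proteins the first siRNA gave -0.09 in the authors' deposited table, inside the range of its matched lists (-0.09 to -0.03), against 0.13 for the second there.

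FAM99B overexpression and DDX21 knockdown shared more genes in the same direction than independent lists would. Of 15395 genes tested in both, 108 were higher in both (19.7 for independent lists) and 56 lower in both (13.7). Opposite calls numbered 32 (29.2) and 12 (9.23). Higher in both were, among others, GBP1, an interferon-induced GTPase (3.41 with FAM99B, 2.77 with the knockdown), the LIM protein FHL2 (2.47, 2.59), TMEM156 (3.32, 2.39), TGFB2-OT1 (2.53, 2.38) and PTGES3L (2.54, 2.36). Lower in both were, among others, ACTN3 (0.495, 0.367), TMPO-AS1 (0.557, 0.497), HAL (0.566, 0.214), TMEM176A (0.566, 0.569) and HP (0.572, 0.428). With the first siRNA in the authors' deposited table, GBP1 was at 1.36, FHL2 at 0.887, TMEM156 at 0.794, PTGES3L at 1.11, ACTN3 at 1.21, HAL at 0.848, TMEM176A at 0.705 and HP at 1.25. Across all shared genes the Spearman correlation of the log2 ratios was 0.12.

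Against the first siRNA, more of the shared mRNAs went opposite ways. In the authors' deposited table, 12 mRNAs were higher with both FAM99B and the first siRNA (5.19 for independent lists) and 6 lower with both (1.44). In contrast, 40 were higher with FAM99B and lower with the first siRNA (4.75), and 9 were lower with FAM99B and higher with it (1.58). The Spearman correlation of these ratios was -0.09, against 0.14 with the second siRNA. In the authors' deposited table, 3 mRNAs were at least 1.5-fold higher in all 3 comparisons, IL9 (FAM99B 1.89, first siRNA 1.88, second 2.17), B3GALT2 (1.56, 1.66, 2.14) and TPM4 (1.56, 2.06, 3.0). Listed as lower in all 3 in the authors' deposited table were 6, of which 5 have a current symbol: the histone genes H3C1 (0.558, 0.304, 0.217), H2AC17 (0.609, 0.579, 0.462) and H2AC4 (0.495, 0.623, 0.518), the ammonium transporter RHBG (0.635, 0.639, 0.164) and SLC51B (0.653, 0.408, 0.612). How many mRNAs independent lists would share in all 3 was not computed, so these small numbers may not exceed it. Both siRNA ratios use the same control library, and these ratios have no counting interval.

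**Figure D3:**
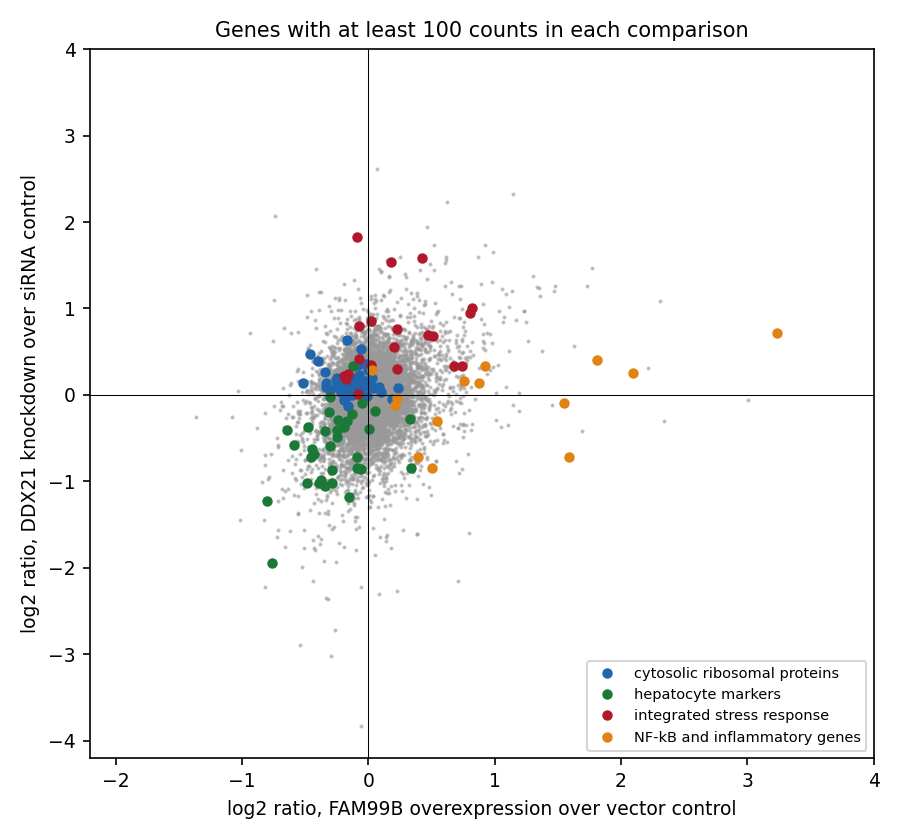
Log2 ratio of each gene with at least 100 counts in both comparisons, FAM99B overexpression against DDX21 knockdown, with 4 gene lists in colour (1 of 12010 genes lies outside the axes). Ribosomal protein genes cluster near the origin, hepatocyte markers lie mostly in the lower left quadrant, and NF-kB genes spread mainly along the FAM99B axis.

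DDX21 ChIP gave 48309 deposited peaks in or near genes, called by the authors. By place, 77.5% lay in introns only, 11.8% within 1 kb of a transcription start and 9.45% in exons. The strongest (hg38) lay on chromosome 21 at 8208748 to 8209551, over MIR3687-1 and beside MIR3648-1, with 420 tags, a deposited fold enrichment of 535 and a deposited false discovery rate of 20%. These microRNA genes lie within copies of the ribosomal RNA gene, so their reads come from many near-identical repeats. Peaks at MIR3648-2 (8986560 to 8986946, 57.3-fold deposited enrichment) and MIR3687-2 (8987510 to 8988234, 45.9-fold) lie in another copy on chromosome 21. A peak in intron 1 of MOB1B, on chromosome 4 at 70927146 to 70933584, had 360 tags and a deposited enrichment of 71.4-fold, with a further one at 70933638 to 70934442 (23.2-fold). Deposited false discovery rates were 20% at MIR3648-2, 10.5% at MIR3687-2, and 20% and 8% for the MOB1B peaks.

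Other strong peaks lay on other chromosomes, and whether the reads of each come from 1 site was not tested. A promoter peak on chromosome 14 at 49586302 to 49586989 (21 tags, 29.0-fold deposited enrichment) covered the starts of both RPS29 and RN7SL1, the 7SL RNA of the signal recognition particle, which has many near-copies in the genome. The rest were in intron 4 of LOC105379117 (chromosome 5, 109486754 to 109487356, 24.8-fold deposited enrichment), across intron 19 and exon 20, with the 3' UTR, of the host gene of MIR1224 by the end of ALG3 (chromosome 3, 184241416 to 184242313, 23.0-fold), in intron 1 of LOC644661 (chromosome 9, 107188018 to 107189212, 22.9-fold) and in intron 3 of SLC35F3 (chromosome 1, 234279014 to 234279965, 22.9-fold). Deposited false discovery rates were 9.52% for the MIR1224 peak and 1.4 to 4% for the other peaks just named. Not among the strongest, a peak lay 299 to 641 bp from the start of DDX21 itself, on chromosome 10 at 68956422 to 68956764. It had a deposited enrichment of 7.5-fold and 6 tags, the lowest number of any deposited peak.

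Ribosomal protein genes had fewer promoter peaks than other genes of like expression. A peak lay within 1 kb of the start in 13 of 79 (16.5%, Wilson interval 9.88 to 26.1%), against 31.6% in matched lists (95% between 21.5 and 41.8%; percentile 0.14). After RPS29 the largest deposited enrichments were at RPL36 (chromosome 19, 5691163 to 5692397, 11.7-fold, shared with LONP1) and RPL38 (chromosome 17, 74203186 to 74203931, 11.4-fold). The RPL36 peak lay 902 to 2136 bp from the start, so only its edge entered the window. Counting only peaks of at least 5-fold deposited enrichment left 5.06% of ribosomal protein genes with one, against 17.7% in matched lists under the same limit (95% between 10.1 and 25.3%). Ribosome biogenesis factors were at 15.9% (percentile 0.715), RNA polymerase I genes at 6.67% (4.31) and G2/M genes at 8.00% (0.890). Proteasome subunits were at 12.9% (1.7) and aminoacyl-tRNA synthetases at 10% (3.2). The shares of these last lists and of RNA polymerase I genes equalled the lower end of their matched ranges. All 10 expressed replication-dependent histone genes had a promoter peak, but they are short and clustered, so the window spans whole genes. A promoter peak was present in 7 of 14 immediate early genes (percentile 98.3), such as JUNB and MYC, and 8 of 16 MYC pathway members (97.6), such as MAX and MLXIPL. Both shares, 50%, equalled the upper end of the matched range and did not exceed it, and MYC is in both lists.

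**Figure D4:**
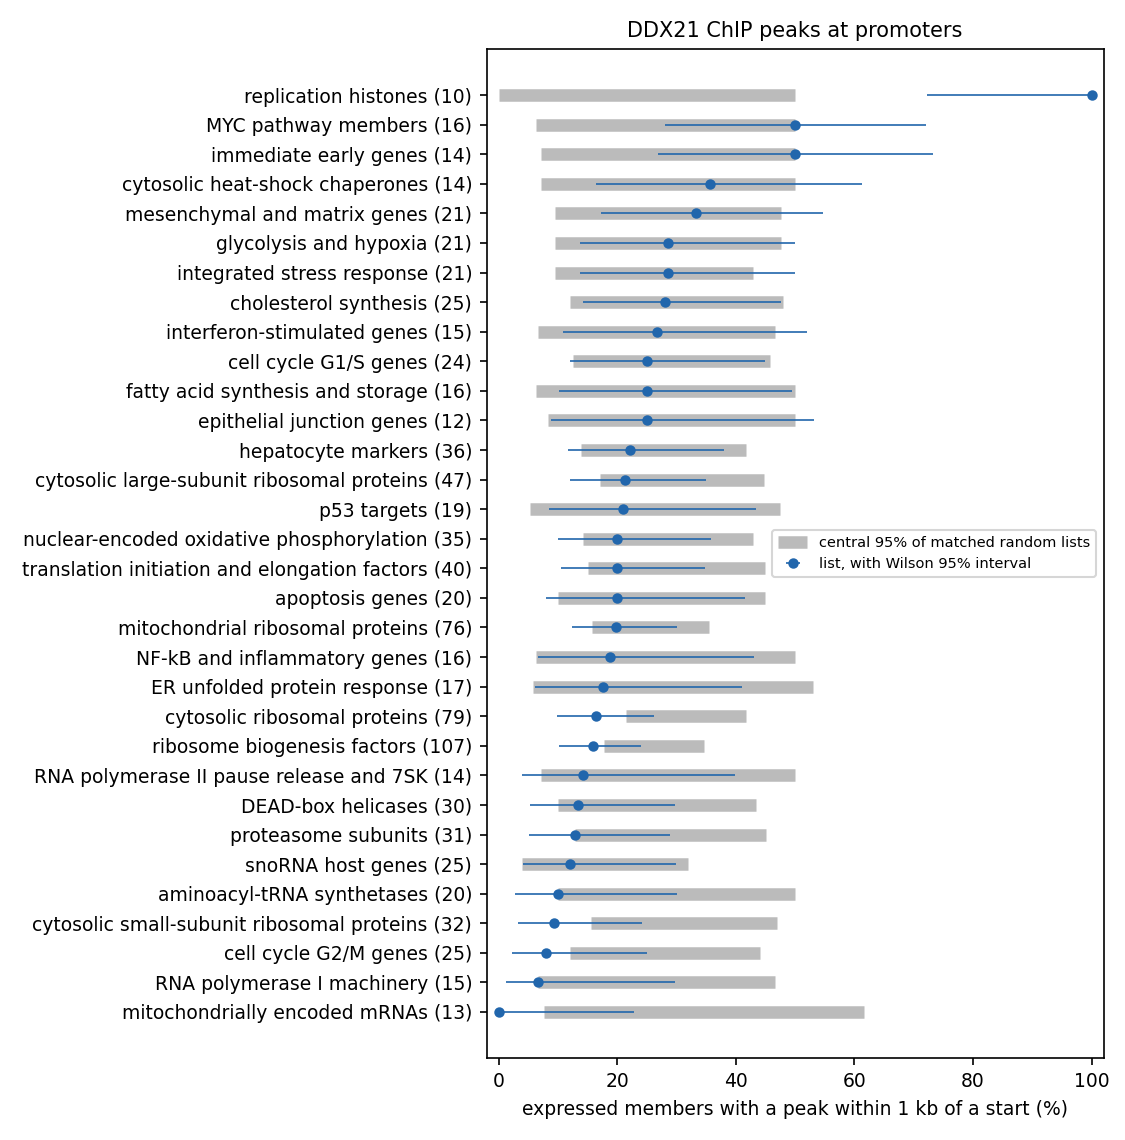
Percent of the expressed members of each gene list (number in brackets) with a DDX21 peak within 1 kb of a transcription start, with the Wilson interval and the range that holds 95% of random lists matched on expression. Replication-dependent histone genes lie above their range, and ribosomal protein and ribosome biogenesis genes below theirs.

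Expressed mRNAs had a promoter peak in 24.7% of cases (23.9 to 25.4%) and mRNAs without counts in 11.8% (11 to 12.7%). Genes with a promoter peak had ratios close to those without: within 10 bins of expression the medians differed by -0.04 on the log2 scale in the knockdown (bootstrap interval over genes -0.06 to -0.01) and by 0.01 with FAM99B (-0.01 to 0.03). The knockdown difference turned to 0.03 when genes with any count were kept. Peaks were thin, with a median of 7 tags, and 46.0% had a deposited false discovery rate above 5%.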

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

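Of the tests in this part, the correlation among well-counted genes and the median of tail-less RNAs were set out in advance, and the others were chosen only after the result was seen. The 2 siRNAs to DDX21 gave list medians of opposite sign in the authors' deposited table for 3 lists. With both siRNAs these medians lay outside the range of their matched lists. The integrated stress response stood at -0.17 with the first siRNA and 0.63 with the second, the replication-dependent histone genes at 0.22 and -0.26, and the mesenchymal and matrix genes at -0.12 and 0.24. The matrix median of the first siRNA lay just below its matched range, which starts at -0.11. By counts, the histone median of the knockdown library, -0.26, lay within its matched range of -0.33 to 0.21. Some histone genes outside that list, H3C1, H2AC17 and H2AC4, were lower with both siRNAs. The difference between the siRNAs was not tested, since each is 1 library.

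The first pattern is this divergence of the siRNAs. A weaker knockdown by the first siRNA and an exchange of its library with the control are both argued against by its DDX21 ratio of 0.269 in the authors' deposited table, below that of the second. The Spearman correlation of the siRNAs was 0.139 among the 4039 mRNAs with at least 1000 counts in the control, where noise is small. Their weak correlation was thus not confined to genes of low count. It covers all such mRNAs rather than the members of the diverging lists, so it cannot decide on counting noise in those lists. What stays open is a part played by counting noise, an effect of either siRNA on other transcripts, or a difference between cultures. No biological explanation was tested, as the design gives none.

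The second pattern is the low median of cytosolic ribosomal protein genes in the FAM99B library. A lower DDX21 mRNA level as its source is argued against by the DDX21 ratio of 1.00. A trend with transcript length may account for part of it: matched on length and expression, the median lay at percentile 6.76, that of the large-subunit genes at 20.7 and that of the small-subunit genes at 2.01. Mitochondrial ribosomal proteins (0.33) and ribosome biogenesis factors (2.39) were also low in that matching. So were lists outside the ribosome, such as proteasome subunits (0.11), cholesterol synthesis (0.46) and G1/S genes (0). Other lists were high, such as epithelial junction genes (99.9). A low median was thus not particular to ribosome genes. The shortest of 10 length bins of other mRNAs had a median log2 ratio of -0.06 against 0.03 for the longest. In the knockdown the trend ran the other way, 0.06 against -0.03. A part specific to ribosomal proteins stays open, since with length matched the random lists had a median of -0.08 against -0.10 for the list.

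The third pattern is the low level of replication-dependent histone genes in the FAM99B library. A lower capture of RNAs without a poly(A) tail stays open. The 172 tail-less small RNA genes had a median of -0.10 (bootstrap interval -0.18 to -0.04) against -0.66 for the histones. They were thus also low, though less so. Whether small RNAs and histone mRNAs are captured alike was not measured, so this median cannot decide it. Short length as the whole source is argued against by a percentile of 0 among lists matched on length and expression. Fewer cells in S phase is a biological hypothesis that may apply, since the G1/S genes had a median of -0.17, below their matched range of -0.07 to 0.05. It was not measured here, and reads shared among histone genes and a difference in culture density stay open and untested.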

How the results depend on the processing

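Of 94 alternative values for the 12 results that answer a comparison, 61 stayed within their interval or limit, 31 moved and 2 reversed; 1 of those that moved also changed sign, from a value whose interval includes 0. Of 2061 values for named genes and lists, 1920 stayed within their interval and 141 moved. These were run with the alternative scalings, added counts and FPKM, and for lists also at least 100 counts, but not with the first siRNA. Under them 14 values changed sign, each the median of a list within its matched range. Restriction to mRNAs and the use of the first siRNA were chosen after the data were seen. Where a rule was made stricter the counts fell by construction, and elsewhere the cause was not tested. At least 100 counts gave 371 genes higher and 157 lower with FAM99B, 466 and 683 in the knockdown, and 29 lower in both. At least 2-fold gave 253, 109, 316 and 500, with 26 higher and 10 lower in both. The whole interval beyond 1.5-fold gave 197, 35, 233 and 372, with 34 and 9 in both. The authors' FPKM with 1 added gave 189 higher and 106 lower with FAM99B, and 52 and 23 in both. Only mRNAs left 161 lower with FAM99B. The first siRNA in the authors' deposited table gave 312 higher and 302 lower, 16 and 12 shared with the FAM99B calls from counts (12 and 6 with the authors' ratios for both), and a ribosomal protein median of -0.0875 in place of 0.13, which changed sign. The ribosomal protein median with FAM99B was -0.0796 with total counts and -0.0795 and -0.0794 with the authors' FPKM plus 0.1 and 1. The difference between genes with and without a promoter peak changed sign in the knockdown to 0.0315 with no minimum, and with FAM99B went from 0.00802 to -0.00847 for the upper part of the peaks. With at least 5-fold enrichment 5.06% of ribosomal protein genes had a promoter peak. A false discovery rate of at most 0.1% was not run, because the lowest in the peak table is 0.32%. No paired analysis was possible because each group has 1 library. Depth limits the siRNA libraries most, with 17311641 and 15777867 counts against 54837446 and 52447391.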

Other observations

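Both tests in this part were chosen only after the result was seen. In the knockdown, where 4.92% of all genes were higher and 7.15% lower, the medians of the interferon, NF-kB, glycolysis, immediate early, apoptosis, p53, epithelial and histone lists lay within the range that holds 95% of matched lists, and those of the MYC, unfolded protein response and helicase lists outside it. Of the calls, 4 of 18 interferon-stimulated genes were higher and 1 lower (median 0.08), with IFI6 at 1.83 and ISG15 at 1.5, and 1 of 16 NF-kB and inflammatory genes was higher and 4 lower (-0.07), with CXCL10, a T cell chemokine, at 0.254 and CCL20 at 0.608. Of 23 glycolysis and hypoxia genes 2 were higher and 4 lower: PFKFB4 was at 0.348 and NDRG1 at 0.414, and in the authors' deposited table also low with the first siRNA (0.396 and 0.679), while ENO2 was at 1.99 (0.630). The median of that list, 0.04, changed sign with at least 100 counts (-0.04). Of 16 MYC pathway members 0 were higher and 2 lower (median 0.24), MLXIPL and MYCN (0.304), with MYC at 1.47. Of 17 ER unfolded protein response genes 0 were higher and 1 lower, XBP1 (0.657; median -0.23). Of 12 epithelial junction genes 0 were higher and 2 lower, the cadherin CDH1 (0.596) and JUP (0.616; median -0.13). Of 14 immediate early genes 2 were higher and 1 lower (0.10), with JUN at 1.56. Of 20 apoptosis genes 1 was higher and 1 lower, the latter BCL2L11 (0.583; median -0.01). Of 19 p53 targets 0 were higher and 2 lower (-0.06), TP53INP1 and SESN1 (0.568). Of 12 replication-dependent histone genes 0 were higher and 2 lower (-0.26), H2BC21 (0.448) and H2BC4 (0.548), and of 30 DEAD-box helicases 1 was lower, DDX21 itself (median 0.14). With the first siRNA in the authors' deposited table, IFI6 was at 0.367, ISG15 at 1.05, CXCL10 at 1.15, CCL20 at 0.899, MYCN at 0.794, MYC at 1.07, XBP1 at 0.922, CDH1 at 1.03, JUP at 0.970, JUN at 0.958, BCL2L11 at 0.910, SESN1 at 1.04, H2BC21 at 1.18 and H2BC4 at 1.15.

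Other lists of the knockdown with 0 calls included the 13 mitochondrially encoded mRNAs (median -0.19), 24 G1/S genes (0.02), 35 nuclear-encoded oxidative phosphorylation genes (0.01), 31 proteasome subunits (0.10), 14 pause release and 7SK genes (0.11) and 7 ribosomal protein-like paralogs (0.21). With FAM99B, other lists with 0 calls included 25 snoRNA hosts (-0.10), 40 translation factors (-0.06), 20 aminoacyl-tRNA synthetases (-0.03), 25 cholesterol synthesis genes (-0.10), 16 fatty acid genes (-0.13), 35 oxidative phosphorylation genes (-0.08), 16 MYC pathway members (-0.08), 14 pause release genes (-0.04), 31 proteasome subunits (-0.13), 30 DEAD-box helicases (-0.05), 21 apoptosis genes (0.10), 12 epithelial junction genes (0.13), 7 ribosomal protein-like paralogs (-0.11) and 14 heat-shock chaperones (0.02, but -0.01 with the size factors of DESeq2). With FAM99B 1 of 19 p53 targets was higher, CDKN1A (1.72; median 0.07), 2 of 19 interferon-stimulated genes, OAS3 (1.98) and IFI6 (1.86; median 0.13), and 1 of 26 glycolysis and hypoxia genes (-0.06), with 0 lower in each. The large-subunit ribosomal proteins had medians of -0.10 with FAM99B and 0.12 in the knockdown, the small-subunit ones -0.13 and 0.14.

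Few markers of other cell types had enough counts, and KRT19, among the cholangiocyte markers, is also in the epithelial list. With FAM99B and in the knockdown, immune markers had medians of 0.17 (5 genes) and -0.23 (3), which turned to -0.07 and 0.58 with at least 100 counts, with 1 higher in each and 0 and 1 lower. CD68, a lysosomal protein of macrophages, was at 2.60 in the knockdown (first siRNA in the authors' deposited table at 1.11). Endothelial markers had medians of -0.09 (5) and -0.51 (3), with 1 higher and 1 lower, PECAM1 (0.420; first siRNA in the authors' deposited table at 1.35), in the knockdown. Cholangiocyte markers had medians of 0.14 (7) and -0.04 (6), with SPP1 the 1 call, higher in the knockdown. Fibroblast and stellate markers were at 0.15 (7) and 0.01 (7), the latter -0.00 with the size factors of DESeq2, and with FAM99B 2 of them were higher, LUM (1.75) and PDGFRA (1.54).

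The genes lower in both comparisons include 2 of the fixed hepatocyte markers, CPS1 and HP, among 56. That number is too small to say whether these genes are a hepatocyte group.

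Genes lower in the knockdown had a promoter peak of DDX21 in 22.9% of 1103 cases, just above the 17.8 to 22.5% of lists matched on expression, and genes higher in it in 21.5%, within their range of 17.2 to 22.8%. Genes called neither way had one in 22.5%, so these shares are close.

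The peaks outside promoters were not spread evenly over the genes of the autosomes: per megabase of gene there were 17.4 on chromosome 8, 47.7 on chromosome 20 and 55.1 on chromosome 19. Of all peaks, 29.3% had the lowest tag number of 6 and 1383 had at least 20. The causes were not tested, and copy number was not available.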
